A study of Mus musculus with 4 samples.

How the data were processed

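RNA of neurospheres from the cortex of C57BL/6 mouse embryos at embryonic day 12.5, passage 3, was profiled in 2 WT and 2 LncBAR-KO libraries. Per the labels' protocols, polyadenylated RNA was selected, converted to complementary DNA with a kit that does not keep strand, and sequenced in 150 bp read pairs. Per the submitters' processing notes, cutadapt 1.16, TopHat2 2.1.1 and Cufflinks 2.2.1 were used with the mm10 build. The tool that counted reads per gene, the annotation release and the treatment of reads with several matches are not given in the sources used here. A kit without strand leaves overlapping genes on opposite strands mixed, and genes with near-identical copies can share reads.

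The authors deposited 1 table of 55599 entries. It gives whole-number counts per gene and library, which per the file headers are read counts and from their values are not normalized. It also gives FPKM values per gene and library, which the authors made from the counts, the gene length in the table and a library size. That library size was recomputed from the values and is proportional to a median-of-ratios size factor. The table further holds the authors' comparison of KO with WT, with a mean signal per genotype (counts divided by size factors), a log2 fold change, a p-value and an adjusted p-value per gene; the tool behind it is not given in the sources used here. Of the entries, 178 are loci without a gene name, 90 of them on assembly patches or scaffolds. For 27 genes the symbol had been turned into a date, and the symbol was restored through the gene identifier from GENCODE M21, which holds 55154 of the identifiers, 54899 of them at the same coordinates. Some genes also have a copy on an assembly patch, between which their reads can be split. No entry was matched to LncBAR by name, so the planned analysis of the targeted RNA was not run.

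The design written before the data were examined assumed FPKM alone and named limma on log2(FPKM + 1), with edgeR to be used if counts were given. Because the table holds counts, the main test was edgeR 4.0.16's quasi-likelihood test in R 4.3.3, with TMM scaling, genotype as the only factor and genes with a mean deposited FPKM of at least 1 over the 4 libraries (12997 genes). P-values were two-sided and adjusted by Benjamini-Hochberg, with 0.05 as the threshold. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. The fit had 2 residual and 8.39 prior degrees of freedom and a common biological coefficient of variation of 7.90%. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so none was used. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested genes, 27 of the 34 fixed, with Benjamini-Hochberg adjustment over these. The lists covered neural stem cells, intermediate progenitors, neurons, astrocytes, oligodendrocytes, dorsal, ventral and posterior identity, proliferation, signalling pathways, stress responses, ribosomal and mitochondrial genes, markers of other cell types and sex-linked check genes, the last given as values only. Similarity was Pearson's r of log2(FPKM + 1).

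Named genes followed a rule written before the data were examined. It takes genes past the threshold whose groups do not overlap, with a mean FPKM of at least 5 in the higher group and a gene symbol, up to 12 in each direction, filled to 8 in each direction by smallest p. From each list that passed it takes up to 4 members past the threshold or else the 2 of smallest p, and from each other list up to 3 members past the threshold or else the member of highest mean FPKM. The sex-linked check genes were always given. Some genes are named outside the rule, among them Arvcf, Dpysl4, Ggcx, Kif11 and Col5a2, and were chosen after their values were seen. Not every such gene is marked where it appears.

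Totals of 17244057 to 18280445 counts differed by a factor of 1.06 between libraries. Where both WT libraries had 0 counts, the fold change is a lower bound against 3 counts per library; this floor covers counting error only, since reads without molecular identifiers are not independent molecules. Counts of every pair of libraries differed by more than sampling noise (chi-square per degree of freedom of 7.68 to 17.7), so no library was counted as a duplicate. The steps were tested on simulated data with the means, library sizes and gene-wise dispersions of these 12997 genes. For KO against WT with 2 libraries each, 68% of 50 genes changed 1.5-fold were recovered, 78% of 50 changed 2-fold and 94% of 50 changed 3-fold and of 50 changed 4-fold, with 19 calls among 12775 unchanged genes, more than 5% of all calls. A list raised 1.3-fold had a camera adjusted p of 2.06e-20, with 0 calls among the other lists. The simulated genes were independent of each other. All these genes and the list were changed at once. The adjusted threshold is then easier to reach than where few genes change, so the shares recovered can overstate those in the real data.

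Alternatives planned before the data were examined were other pseudocounts, no filter and a filter at a mean FPKM of 5, median-of-ratios scaling, rescaling of FPKM to a fixed sum, quantile normalization, other empirical Bayes settings, a replicate block, leaving out each library, other thresholds, camera with an estimated correlation, fry and Spearman's correlation. Those on pseudocount, rescaling, quantile normalization and empirical Bayes were applied to the limma fit. Added after seeing the data were limma on log2(FPKM + 1) itself, DESeq2 1.42.0, filterByExpr, total counts without TMM, robust edgeR, log2 CPM for similarity, and fits without chromosomes X and Y or without patches and unnamed loci.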

Results

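Polyadenylated RNA was measured in neurospheres, the free-floating clusters that neural stem and progenitor cells form in culture. They were grown from the cortex of C57BL/6 mouse embryos at embryonic day 12.5 and taken at passage 3. The 4 libraries were 2 from wild-type (WT) and 2 from knockout (KO) cells lacking the long noncoding RNA LncBAR. The deposited gene counts added up to 17897932 and 17244057 in WT replicates 1 and 2 and to 17392157 and 18280445 in KO replicates 1 and 2. The labels do not say whether the 2 libraries of a genotype came from separate embryos or cultures, so p-values measure the spread between these libraries, which may be technical. Expression is given as CPM (counts relative to the TMM-scaled library size), mean ± SD with n = 2 libraries per genotype. Log2 fold changes are KO over WT with their SE from edgeR's quasi-likelihood test, and adjusted p-values are Benjamini-Hochberg values from that test over 12997 genes. The labels name no gene identifier for LncBAR and no entry of the table was matched to it by name. Its level in the WT and KO libraries was not analysed here and the genotype labels were not checked against it.

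The comparison of KO with WT neurospheres asks which genes change expression when LncBAR is missing. The genes that changed among those past the expression filter lay almost entirely on the sex chromosomes; without the filter 15 of 31 called genes were autosomal. Xist, the noncoding RNA that coats the inactive X chromosome in female cells, fell from 1933 ± 165 CPM in WT to 0.312 ± 0.127 CPM in KO (n = 2 each). Its counts were 36766 and 31563 in the WT libraries and 7 and 4 in the KO libraries. Ddx3y (an RNA helicase), Eif2s3y (a subunit of translation initiation factor eIF2), Kdm5d (a histone H3K4 demethylase) and Uty (the Y-linked relative of the H3K27 demethylase Kdm6a) had 0 counts in both WT libraries. They rose to 94.1 ± 11.7, 58.1 ± 2.96, 55.2 ± 0.878 and 29.5 ± 0.168 CPM in KO (n = 2). The X-linked partners of 3 of these genes fell: Kdm6a from 101 ± 5.81 to 57.8 ± 1.86 CPM, Kdm5c from 280.1 ± 8.03 to 168 ± 6.48 CPM and Eif2s3x from 223 ± 4.44 to 147 ± 10.9 CPM (n = 2 each).

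Of 12997 genes tested, 9 passed an adjusted p of 0.05 in edgeR, 5 higher and 4 lower in KO. Xist had a log2 fold change of -12.57 ± 0.18 (adjusted p = 4.35e-11). Against a floor of 3 counts per library in WT, Ddx3y was at least 553-fold, Eif2s3y at least 342-fold, Kdm5d at least 325-fold and Uty at least 174-fold higher in KO. Their adjusted p-values in edgeR were 2.14e-08 for the first 3 genes and 2.65e-07 for Uty. Kdm6a had a log2 fold change of -0.80 ± 0.08 (adjusted p = 0.00316), Kdm5c of -0.74 ± 0.08 (adjusted p = 0.00421) and Eif2s3x of -0.60 ± 0.08 (adjusted p = 0.0389). The X genes lie, in mm10 coordinates of the table, on chromosome X at 103460366 to 103483254 (Xist), 18162575 to 18279936 (Kdm6a), 152233020 to 152274535 (Kdm5c) and 94188707 to 94212862 (Eif2s3x). The Y genes lie on chromosome Y at 1260771 to 1286629 (Ddx3y), 1010543 to 1028847 (Eif2s3y), 897788 to 956786 (Kdm5d) and 1096861 to 1245759 (Uty). The remaining call was a locus without a gene name on an assembly patch, from 6363676 to 6378587, outside the rule for named genes and named after its values were seen. It rose from 14.5 ± 1.75 to 34.2 ± 2.71 CPM (log2 fold change 1.23 ± 0.12, adjusted p = 0.00241).

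Each library carried the sex-chromosome pattern of its genotype group, and the labels give no sex of the embryos. The 4 Y genes together had 0 counts in each WT library, 3962 in KO replicate 1 and 4449 in KO replicate 2. All named Y genes together had 315 and 283 counts in WT and 4227 and 4651 in KO, of which Gm47283 had 287, 248, 216 and 139 in the same order. Eif2s3x had 3941 and 3926 counts in the WT libraries in which Eif2s3y had 0, so reads of the X copy were not counted for the Y copy there. Over the 441 tested X genes the median log2 fold change was 0.01, and 4 of them passed the test. Xist is overlapped by its antisense gene Tsix and the kit did not keep strand, so reads of these genes could not be told apart. With Xist and Y genes divided this way, no comparison of KO with WT in these libraries separates genotype from the sex-chromosome difference. In limma on log2(FPKM + 1) Uty and the 3 X-linked partner genes did not pass, with adjusted p of 0.0725 for Uty, 0.171 for Kdm6a, 0.154 for Kdm5c and 0.399 for Eif2s3x. Without KO replicate 1 Eif2s3x had an adjusted p of 0.0608 in edgeR.

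**Figure D1:**
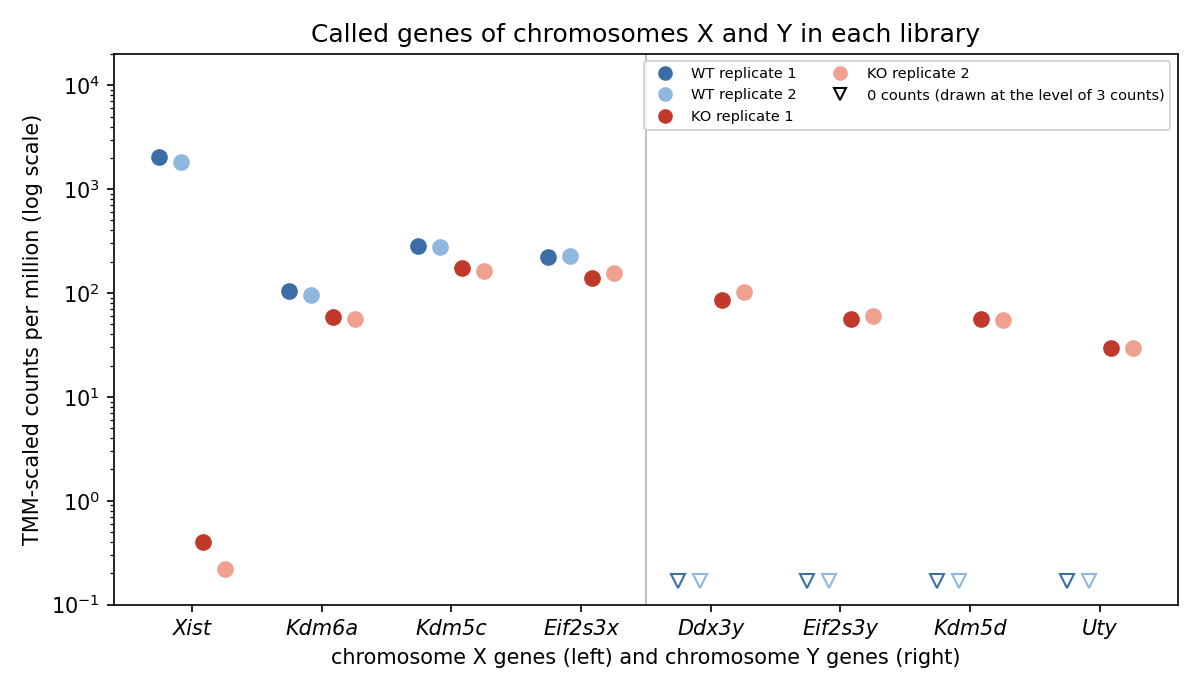
Expression (TMM-scaled CPM) on a log axis for the 8 called genes of chromosomes X and Y, with 1 point per library and open triangles at the level of 3 counts for libraries with 0 counts. Xist had 36766 and 31563 counts in WT against 7 and 4 in KO, and the 4 Y genes had 0 counts in both WT libraries.

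On the autosomes the WT and KO neurospheres differed little. None of 12413 autosomal genes passed in edgeR, while 705 had an unadjusted p under 0.05 where chance gives about 621. DESeq2 called 2 (Rps14 and Arvcf) and limma on log2(FPKM + 1) called 0. The smallest autosomal adjusted p in edgeR was 0.124, that of Arvcf, a catenin of the p120 family, at 5.99 ± 1.23 CPM in WT and 14.7 ± 3.27 CPM in KO (n = 2, log2 fold change 1.29 ± 0.21). Summed with a locus of nearly the same coordinates on an assembly patch, Arvcf had a log2 fold change of 0.61 ± 0.16 (adjusted p = 0.811). For 91.3% of the autosomal genes the 95% interval of the fold change lay within a 2-fold change in either direction. The genes of smallest p that the naming rule adds did not pass (adjusted p of 0.698 to 0.811 in edgeR). Those higher in KO were the ribosomal protein genes Rps14 (0.36 ± 0.08), Rpl30 (0.31 ± 0.08) and Rpl17 (0.63 ± 0.16). Rpl17 differed between the WT libraries, at 157 CPM in WT replicate 1 and 102 CPM in WT replicate 2. Higher too were the mitochondrial ribosomal RNA mt-Rnr1 (0.48 ± 0.12), Kcnip1 (0.40 ± 0.10), which encodes a potassium channel interacting protein, and the spliceosome component Bud31 (0.35 ± 0.09), all as log2 fold change ± SE. Those lower in KO were the kinase gene Hipk2 (-0.49 ± 0.11), Gm9824 (-0.53 ± 0.12), the CREB coactivator Crtc3 (-0.41 ± 0.09) and the proteasome activator subunit Psme2 (-0.52 ± 0.12). Leaving out 1 library raised the number of autosomal calls in edgeR, to 63 without WT replicate 1, 29 without WT replicate 2, 9 without KO replicate 1 and 5 without KO replicate 2. In such a fit the lone library is assumed to vary like the pair of the other genotype, so these calls can reflect 1 library. Without the filter on low expression 15 autosomal genes passed in edgeR, among them Rpl17 (adjusted p = 0.0284) and Hipk2 (adjusted p = 0.0425). Both lay above the filter and had edgeR adjusted p of 0.811 and 0.698 in the main fit. Their log2 fold changes hardly differed without the filter (0.64 and -0.48), so the lower p-values are no sign of a larger change. Why the p-values fell was not tested.

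The authors' deposited table lists 13 genes or loci at an adjusted p under 0.05, 8 higher and 5 lower in KO, and all 9 edgeR calls are among them. Its 4 autosomal genes include Dpysl4, a member of the family of dihydropyrimidinase-like proteins that act in axon growth, with a log2 fold change of -2.70 and an adjusted p of 2.48e-08 there. The others are Arvcf (adjusted p = 0.00195 there), the vitamin K dependent carboxylase gene Ggcx (2.32) and Rps14 (0.36). Dpysl4 and Ggcx lay below the expression filter used here, with 163, 124, 25 and 19 counts for Dpysl4 and 20, 10, 86 and 63 counts for Ggcx in WT replicates 1 and 2 and KO replicates 1 and 2.

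The second question was whether groups of genes fixed before the data were examined shifted together. Of 27 lists tested, 5 passed in camera with a preset correlation of 0.01, all higher in KO, though no single member passed over all genes. None of the 5 passed when camera estimated the correlation between genes (adjusted p of 0.933 to 0.970). That form of camera was limited to the 2 residual degrees of freedom of the fit, so a list could hardly pass. Its adjusted p-values, here and below, therefore do not decide whether a list shifted. The estimated correlations of the 5 lists were 0.18 to 0.93, above the preset 0.01, so the camera p-values at the preset may overstate the evidence. Among cytosolic ribosomal proteins, 78 of 80 genes had a positive fold change with a median log2 fold change of 0.19 (camera adjusted p = 5.69e-21), Rps14 and Rpl17 having the smallest p. All 15 mitochondrially encoded genes had a positive fold change, with a median of 0.18 (camera adjusted p = 0.000121), and mt-Rnr1 and mt-Rnr2 (0.31 ± 0.13) had the smallest p. The integrated stress and unfolded protein response list had 14 of 15 genes positive and a median of 0.18 (camera adjusted p = 0.00224), among them the asparagine synthetase gene Asns (0.40 ± 0.16) and the endoplasmic reticulum chaperone gene Hspa5 (0.19 ± 0.08). Of the p53 targets 16 of 19 were positive with a median of 0.13 (camera adjusted p = 0.0235), with Ccng1 at 0.23 ± 0.08 and Plk2 at 0.19 ± 0.08. The hypoxia and glycolysis list had 17 of 19 genes positive and a median of 0.17 (camera adjusted p = 0.0235), with Tpi1 at 0.23 ± 0.11. Gapdh, in the same list, was at -1.81 ± 0.59 because it stood at 54.3 CPM in WT replicate 1 and at 8.69, 8.55 and 9.42 CPM in the other libraries. Gapdh has many pseudogenes, and whether they share its reads was not examined here, so this value is uncertain.

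The calls were made at the preset correlation and depended on other settings. The adjusted p with an estimated correlation was 0.933 for the ribosomal protein, mitochondrial, stress response and p53 lists and 0.970 for the hypoxia and glycolysis list. Fry, which rests on the same 2 residual degrees of freedom, called 0 lists, and this does not decide whether a list shifted either. With quantile normalization the mitochondrially encoded genes (median 0.0588, camera adjusted p = 0.0945), the p53 targets (median 0.0715, camera adjusted p = 0.0945) and the hypoxia and glycolysis list (median 0.0986, camera adjusted p = 0.213) did not pass. The p53 targets did not pass at a mean FPKM of at least 5 (camera adjusted p = 0.0570), and the hypoxia and glycolysis list did not with a pseudocount of 0.1 (camera adjusted p = 0.0590) or in robust edgeR (camera adjusted p = 0.0615). The cytosolic ribosomal proteins passed with a lower median, 0.0667 with quantile normalization and 0.12 with rescaled FPKM. Adjusted over the list alone, 1 mitochondrially encoded gene (mt-Rnr1) rose and no member of the other 4 lists passed. Single libraries carried part of each shift. The ribosomal protein genes deviated from the mean of the 4 libraries by a median log2 of -0.11 in WT replicate 1, -0.08 in WT replicate 2, 0.01 in KO replicate 1 and 0.19 in KO replicate 2. Their share of all counts was 3.92%, 4.01%, 4.23% and 4.70% in the same order. The mitochondrial list had a median log2 fold change of 0.04 without KO replicate 2 (camera adjusted p = 0.309). The share of counts from mitochondrially encoded genes was 3.15% and 3.28% in WT and 3.31% and 3.87% in KO. WT replicate 2 was low in the integrated stress and unfolded protein response, the p53 targets and the hypoxia and glycolysis lists. Without it the median was 0.03 for the stress response list (camera adjusted p = 0.631) and 0.07 for p53 targets (camera adjusted p = 0.512). The hypoxia and glycolysis list turned to -0.11 (camera adjusted p = 5.93e-06). Without KO replicate 1 these 3 lists did not pass, with camera adjusted p of 0.0604, 0.159 and 0.642.

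**Figure D2:**
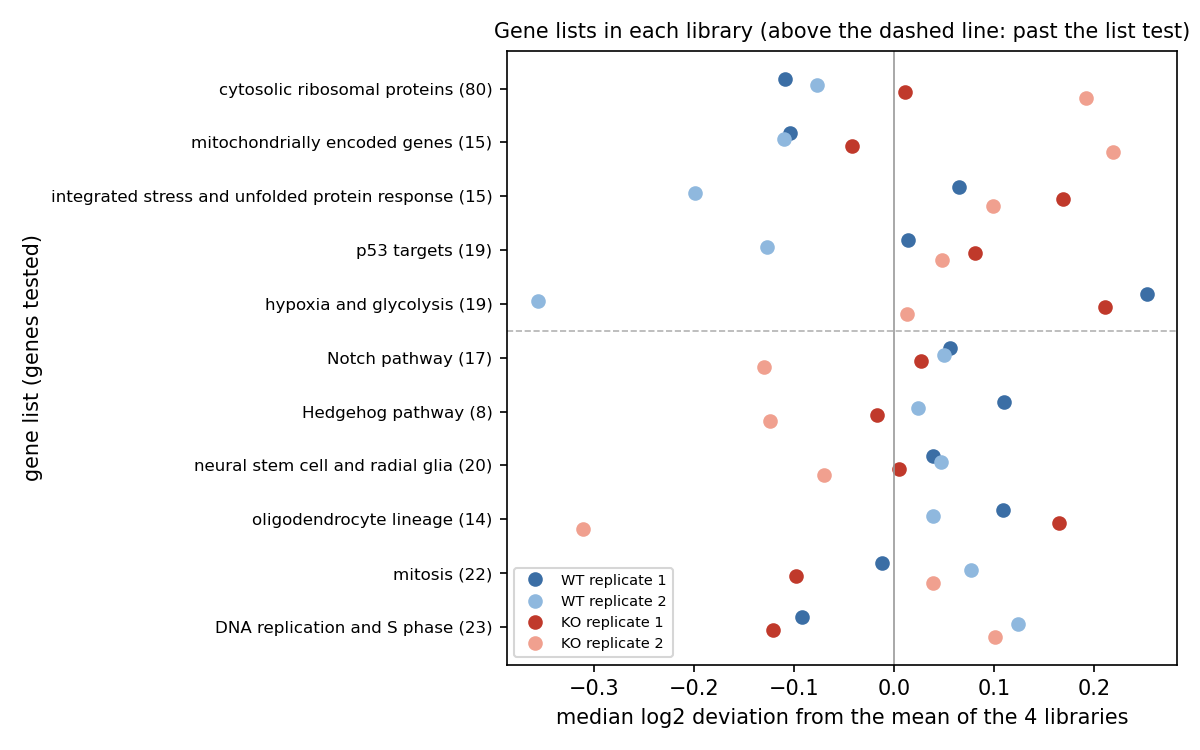
Median log2 deviation of each gene list from the mean of the 4 libraries, with 1 point per library, the number of genes tested in brackets and the lists that passed camera above the dashed line. In the hypoxia and glycolysis list WT replicate 2 lies at -0.36 and WT replicate 1 at 0.25, on either side of the KO libraries at 0.21 and 0.01.

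Lists of genes that mark the identity of the cells did not pass camera in edgeR with the expression filter, and 3 of them passed, lower in KO, in another setting. The neural stem cell and radial glia list had 20 of 20 genes tested and a median log2 fold change of -0.04 (camera adjusted p = 0.219). Its member of highest mean FPKM, the brain lipid binding protein gene Fabp7, stood at 1719 ± 45.0 CPM in WT and 1936 ± 106 CPM in KO (n = 2). The medians were -0.07 for intermediate progenitor and proneural genes (Gadd45g at 0.11 ± 0.08), -0.04 for dorsal telencephalon patterning (Nr2f1 at -0.09 ± 0.09), -0.06 for astrocyte genes (Sparcl1 at -0.01 ± 0.09) and -0.14 for the oligodendrocyte lineage (Olig1 at 0.06 ± 0.08), with camera adjusted p of 0.341, 0.864, 0.681 and 0.378. Neuron genes had a median of -0.05, a mean of 0.02 and an upward test direction (camera adjusted p = 0.953), with Gap43 at 0.30 ± 0.12. The oligodendrocyte lineage list deviated by -0.31 in KO replicate 2 alone, against 0.16 in KO replicate 1. It passed without KO replicate 1 (median -0.42, camera adjusted p = 7.44e-06), and the neural stem cell and radial glia list passed with quantile normalization (median -0.13, camera adjusted p = 0.00870). With an estimated correlation in the fit of all 4 libraries the camera adjusted p was 0.974 for the oligodendrocyte lineage and 0.933 for the neural stem cell list. In the ventral telencephalon and GABA neuron list only 4 of 15 genes were expressed enough to be tested, too few for a list test. Without the filter 13 were tested and the list passed (median -0.67, camera adjusted p = 0.000773). With filterByExpr 11 were tested and it passed as well (median -0.68, camera adjusted p = 0.00358). The genes added in these fits lay below the expression filter, so both medians rest largely on genes of low expression. They do not show a loss of such cells in KO. Adjusted over the list alone, 2 of the 4 genes that reached the filter fell, Dlx6 (-0.78 ± 0.25) and Gsx2 (-0.71 ± 0.25). Both had an edgeR adjusted p of 0.811 over all genes and were named after their values were seen.

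Lists of proliferation genes and signalling pathways did not pass in edgeR with the filter, and some passed in other settings. Mitosis genes had a median of -0.05 (camera adjusted p = 0.0813, with Cdc20 at -0.05 ± 0.08). Adjusted over the list alone 1 of 22 fell, the spindle motor gene Kif11 (-0.66 ± 0.15), which did not pass over all genes (edgeR adjusted p = 0.756). DNA replication genes had a median of -0.02 (camera adjusted p = 0.864; Pcna at 0.04 ± 0.12) and cyclin-dependent kinase inhibitors of 0.14 (camera adjusted p = 0.0975; Cdkn1a at 0.16 ± 0.08). The Notch list had 12 of 17 genes negative and a median of -0.10, and the Hedgehog list 7 of 8 genes negative and a median of -0.13, each with a camera adjusted p of 0.0579. Lfng stood at 0.02 ± 0.09 and Gas1 at 0.05 ± 0.08 as the members of highest mean FPKM. Both lists passed in limma on log2(FPKM + 1) and without chromosomes X and Y (camera adjusted p of 0.0404 and 0.0138 for each). In all the Notch list passed in 11 settings and the Hedgehog list in 7, lower in KO in each, with camera adjusted p of 0.00191 to 0.0482 and 0.0138 to 0.0482. These settings draw on the same 4 libraries and several are variants of 1 limma fit, so the passes are not separate support. With an estimated correlation the camera adjusted p was 0.933 for both lists. The Notch median was -0.20 without KO replicate 1. Mitosis genes passed, lower in KO, with rescaled FPKM, with quantile normalization, without WT replicate 1, without KO replicate 2 and without chromosomes X and Y (medians of -0.13 to -0.05, camera adjusted p of 0.000142 to 0.0244). Cyclin-dependent kinase inhibitors passed, higher in KO, without KO replicate 2 and without chromosomes X and Y (camera adjusted p of 0.0223 and 0.0285). DNA replication genes passed, lower in KO, without WT replicate 1 and without KO replicate 2 (medians of -0.13 and -0.14, camera adjusted p of 0.00167 and 0.000929). With an estimated correlation the adjusted p was 0.974 for DNA replication genes, 0.970 for mitosis genes and 0.933 for cyclin-dependent kinase inhibitors. Wnt genes (median -0.04, mean -0.0011, upward test direction; Ccnd1 at 0.11 ± 0.10), BMP genes (0.05; Id3 at -0.03 ± 0.08) and TGF-beta genes (median -0.03, mean 0.02, upward test direction; Smad4 at -0.12 ± 0.08) had camera adjusted p of 0.953, 0.936 and 0.953.

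The other lists gave no call in edgeR with the filter. Immediate early genes passed, higher in KO, without WT replicate 1 and without KO replicate 2 (medians of 0.20 and 0.16, camera adjusted p of 5.99e-05 and 0.000912). Replication-dependent histones passed, higher in KO, with rescaled FPKM (median 0.03, camera adjusted p = 0.0174). With an estimated correlation in the fit of all 4 libraries the camera adjusted p was 0.974 for immediate early genes and 0.933 for these histones. Median log2 fold changes and camera adjusted p were -0.03 and 0.575 for the Lin28 and let-7 axis (Hmga1 at 0.13 ± 0.08), 0.10 and 0.508 for replication-dependent histones (Hist1h1c at 0.05 ± 0.09), -0.13 and 0.219 for clustered protocadherins (Pcdhgc3 at -0.15 ± 0.08) and 0.05 and 0.508 for immediate early genes (Nr4a1 at 0.07 ± 0.10). Imprinted genes (median 0.02, mean -0.0013, downward test direction; Nnat at -0.02 ± 0.09) and cholesterol biosynthesis genes (median 0.01, mean -0.01, downward test direction; Hmgcs1 at 0.03 ± 0.08) each had a camera adjusted p of 0.964. Interferon response and MHC class I genes had a median of -0.05, a mean of -0.01 and an upward test direction (camera adjusted p = 0.936; B2m at 0.17 ± 0.09). Few or none of the markers of microglia, erythroid cells, endothelium, choroid plexus and ependyma, and posterior regions were expressed enough to be tested. None of 12 microglia and 9 erythroid genes reached the expression filter. Without the filter 7 microglia and myeloid genes were tested and the list passed, higher in KO (median 2.32, camera adjusted p = 0.0432). That fit takes any gene with at least 1 count, and all 7 lay below the expression filter. The median thus rests on genes of low expression and does not show more such cells in KO. Of 10 endothelial genes 1 reached the filter (Egfl7, 4.14 ± 1.71 CPM in WT and 4.84 ± 1.67 CPM in KO). So did 1 of 10 choroid plexus and ependyma genes (Foxj1, 21.8 ± 4.70 and 23.9 ± 2.64 CPM) and 1 of 26 posterior regional identity genes (Gbx2, 4.17 ± 0.295 and 3.40 ± 1.07 CPM), with n = 2 per genotype. Of 18 extracellular matrix and mesenchyme genes 7 were tested (median 0.01, mean -0.06, downward test direction, camera adjusted p = 0.508, with Fbn1 at -0.23 ± 0.08). Adjusted over the list alone the collagen gene Col5a2 fell (-0.77 ± 0.18), but it did not pass over all genes (edgeR adjusted p = 0.806).

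The last question was whether libraries of 1 genotype resemble each other more than those of different genotypes. Pearson's r of log2(FPKM + 1) across the tested genes, which are not independent replicates, was 0.987 for both pairs of the same genotype and between 0.983 and 0.987 for the 4 pairs of different genotypes. Without the genes of chromosomes X and Y the pairs of the same genotype had r of 0.986, inside the range of 0.985 to 0.988 for pairs of different genotypes. KO replicate 1 was then closer to WT replicate 1 (r = 0.988) than to KO replicate 2 (r = 0.986). No test was made of these values.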

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

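The fits without chromosomes X and Y, without patches and unnamed loci, with DESeq2, filterByExpr, total counts, robust edgeR or log2 CPM, and limma on log2(FPKM + 1), were chosen after seeing the data; the others were fixed before the data were examined. The other ways of measuring the targeted lncRNA fixed beforehand were not run, since no entry was matched to it. Where nothing else is said the cause was not tested. The 9 called genes passed in 139 of 177 runs of an alternative and none changed sign; Xist, Ddx3y and Eif2s3y were the 3 that limma called in most of its settings. Against 9 genes (5 higher and 4 lower in KO, 8 on X and Y, 0 on autosomes) and 5 lists in edgeR, limma on log2(FPKM + 1) called 4 genes (3 higher, 1 lower, 4 on X and Y), and pseudocounts of 0.1 and 0.5, the rescaling of FPKM and quantile normalization each called 3 (2 higher, 1 lower, 3 on X and Y). Without trend limma called 5 (1 lower, 5 on X and Y), and with the robust option 1 lower gene, 5 on X and Y and 2 on autosomes. Without the filter edgeR called 31 genes (15 higher, 16 lower, 15 autosomal) and 8 lists, among 29222 genes tested; the 9 genes were all among the 31. A mean FPKM of 5 left 2 higher genes, since fewer genes were tested. DESeq2 called 8 higher and 2 autosomal genes, robust edgeR 1 autosomal gene (Arvcf) and filterByExpr 1 (Dpysl4). At 2-fold or more 1 lower gene and 5 on X and Y were left. Without chromosomes X and Y, by construction, 1 gene was called (1 higher, 0 lower, the unnamed locus), with 9 lists.

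Camera with an estimated correlation and fry each called 0 lists. Both rest on the 2 residual degrees of freedom of the same fit, which left little room for a call. With a replicate block edgeR called 24 genes (13 higher, 11 lower, 11 autosomal) and 8 lists, cyclin-dependent kinase inhibitors (camera adjusted p = 0.0424) among them. The labels do not say that a number pairs libraries, and the differences between replicates 1 and 2 in WT and in KO correlated at 0.088 across genes, so the numbers were not taken as pairs. Leaving out 1 library gave 15 to 86 genes, 9 to 62 higher, 6 to 26 lower, 5 to 63 autosomal and 8 to 10 on X and Y, and 3 to 9 lists; the lone library is then assumed to vary like the pair of the other genotype. As to the similarity of libraries, the mean r within genotypes exceeded that between them by 0.00191, by 0.000527 without chromosomes X and Y and by 0.0034 on log2 CPM.

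Of 43 named genes that did not pass, 8 passed in some alternative, and signs turned in 41 of 898 runs, all at values that did not pass. With rescaled FPKM these were Olig1 (-0.00534), Pcna (-0.0236), Lfng (-0.0476), Gas1 (-0.0214), Hist1h1c (-0.0201) and Hmgcs1 (-0.0331), and with quantile normalization Olig1 (-0.0880), Pcna (-0.0397), Lfng (-0.0185), Ccnd1 (-0.0821), Gas1 (-0.000358), Hist1h1c (-0.00961), Nr4a1 (-0.0248) and Hmgcs1 (-0.0496). Sparcl1 was at 0.00617 without the filter, 0.00126 with filterByExpr and 0.0011 in the limma fits with pseudocounts of 0.1, 0.5 and 1, without trend and with the robust option. Leaving out 1 library gave ranges across 0 for Sparcl1 (-0.0933 to 0.0794), Pcna (-0.12 to 0.225), Lfng (-0.0676 to 0.11), Gas1 (-0.0132 to 0.11), Hist1h1c (-0.0410 to 0.14), Hmgcs1 (-0.00483 to 0.0746), Ccnd1 (-0.0329 to 0.24), Nr4a1 (-0.0498 to 0.20), Foxj1 (-0.0703 to 0.37), Id3 (-0.0949 to 0.0442), Nnat (-0.10 to 0.064), Egfl7 (-0.18 to 0.72), Nr2f1 (-0.19 to 0.00214), Gapdh (-2.60 to 0.0478) and the hypoxia and glycolysis list (-0.11 to 0.45). Depth limits genes of few counts, such as Stk32c with 7 and 4 counts in KO.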

Other observations

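Genes below the expression filter, or close to it, held the autosomal differences of largest size. Without the filter edgeR called 15 autosomal genes, 7 higher and 8 lower in KO. Dpysl4 fell (log2 fold change -2.69 ± 0.26, adjusted p = 4.65e-07 in edgeR without the filter) and its neighbour Stk32c, a serine/threonine kinase gene, fell too (-2.79 ± 0.48, adjusted p = 0.00741). Six3os1, the antisense noncoding RNA beside the forebrain regulator Six3, had 259 and 153 counts in WT and 1 and 60 in KO (adjusted p = 0.00343). Ggcx (adjusted p = 0.000502) and Arvcf (adjusted p = 0.000699) rose, and so did Auts2, a gene linked to neurodevelopment, with 32 and 49 counts in WT and 89 and 109 in KO (adjusted p = 0.0405). Lower in KO at higher counts was Col5a2, with 1062 and 1029 counts in WT and 761 and 467 in KO (adjusted p = 0.0151 without the filter). The transcriptional repressor gene Zbtb20 had 1044 and 904 counts in WT and 704 and 644 in KO (adjusted p = 0.0341 without the filter). Both were also tested with the filter, where neither passed in edgeR. There Col5a2 had an adjusted p of 0.806 and no autosomal gene one below 0.124. All genes named in this paragraph were chosen after their values were seen.

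Arvcf shares most of its coordinates with a locus without a gene name on an assembly patch, which starts 16 bp away, and counts summed over both were 267 and 251 in WT and 454 and 340 in KO. Haus1 had 18, 14, 257 and 18 counts in WT replicates 1 and 2 and KO replicates 1 and 2, so that 1 library gave its higher mean in KO.

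Of the tests below, those of the sex-chromosome genes, gene length, the single library, neighbour placement and shared reads were chosen after the results were seen, and that of GC content before. The first pattern was the difference in genes of chromosomes X and Y. Kdm5c, Kdm6a, Eif2s3x and Ddx3x, which escape X inactivation in mouse cells, had a median log2 fold change of -0.67, with Ddx3x alone at -0.19 ± 0.09 and not past the threshold, and the 4 Y genes had 0 counts over the WT libraries. Loss of LncBAR between cells of one sex is argued against by these 0 counts, since it would leave these 4 Y genes expressed in both genotypes or in neither. A candidate explanation is that the WT libraries came from female and the KO libraries from male embryos. What stays open is how far any other difference between the groups belongs to the genotype, since each genotype has 1 pattern only.

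The second pattern was the higher level of cytosolic ribosomal protein genes in the KO libraries, with a median log2 fold change of 0.19. Across all tested genes the fold change fell with gene length (Spearman's rho -0.28, over genes, which are not independent), and ribosomal protein genes are short, with a median length of 1806 bp against 4058 bp. After each library's trend with gene length was removed the list kept a median of 0.14 (camera adjusted p = 2.65e-12). This covers the deposited gene length and not the length of the transcripts present, so transcript length stays open as a cause. The trend was also seen between libraries of 1 genotype. From short to long genes the median log2 ratio of KO replicate 2 to KO replicate 1 fell from 0.06 to -0.05. That of WT replicate 2 to WT replicate 1 fell from 0.04 to -0.03. After the trend with GC content was removed the list had a median of 0.19 (camera adjusted p = 4.88e-21). The GC content was that of the longest GENCODE M21 transcript of each gene. The median kept argues against this GC content as the whole cause but does not cover that of the transcripts present. Without KO replicate 2 the median was 0.10 (camera adjusted p = 3.36e-06), which lies above the median difference of 0.02 between the WT libraries and below that of 0.18 between the KO libraries, so it cannot be told apart from the spread between libraries of a genotype. The genotype, the sex of the cells and the state of the cultures at harvest stay open. With an estimated correlation the camera adjusted p of the list was 0.933, which on 2 residual degrees of freedom decides little.

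The third pattern was the drop of the neighbours Dpysl4 and Stk32c, which lie on chromosome 7 at 139086001 to 139102704 and 139103638 to 139213307 (mm10), with their 3′ ends 934 bp apart on opposite strands. The 15 autosomal genes called without the filter held 2 pairs of neighbours within 50000 bp (Haus1 and Pstpip2 being the other), and random sets of 15 expressed autosomal genes seldom held as many (permutation p = 0.000200). This decides nothing on chance placement, since the count includes the pair that prompted it and the other pair rests on Haus1, whose groups overlap. Whether reads running past the end of Dpysl4 were counted for Stk32c cannot be told apart from a drop of both: Stk32c made up 21.4% of their joint counts in WT and 20.0% in KO (Fisher's exact p = 1, two-sided, 95% interval of the odds ratio 0.409 to 1.92), but 25.2% and 15.6% in the 2 WT libraries (p = 0.0368), so the interval covers counting error only and understates the spread. Sex and genotype cannot be told apart here either, since 0 libraries departed from the sex-chromosome pattern of their genotype, and a difference in genetic background at this locus was not tested.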
